A study of Citrus sinensis with 6 samples.

How the data were processed

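RNA from the albedo of sweet orange fruit (Citrus sinensis) was sequenced in 6 libraries. The albedo is the white inner layer of the peel, and per the labels it was excised 3 days after inoculation. In 3 libraries the treatment was the antagonist yeast Rhodotorula mucilaginosa together with 0.2 mM salicylic acid, a plant defence hormone, and in the other 3 it was the yeast alone. Groups and replicate numbers were taken from the sample titles. The labels do not say with what the fruit was inoculated, nor whether the libraries come from separate fruit, so the p-values measure only the spread between these samples, which may be technical. No untreated fruit was analysed here.

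Per the labels' protocols, total RNA was sequenced on an Illumina HiSeq instrument. The aligner, the assembler and the genome build are not given in the sources used here. Per the file headers, each library has a transcript table with an FPKM value and a mean per-base coverage for each transcript. Its columns and the MSTRG identifiers are of the kind that StringTie writes for ballgown after annotated and newly assembled transcripts are merged, and replicates were not pooled. The deposited coverage is a signal that was not normalized, and the deposited FPKM is a fixed multiple of it within each library. The ratio of coverage to FPKM gives the depth of each library in gigabases.

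A deposited gene table also holds a value for each gene and library, in a unit of its own. These gene values were recomputed from the transcript tables for 15778 genes. In 88.4% of them, 13950 genes, the summed product of FPKM and transcript length divided by the deposited value was constant over libraries within 0.1%, and 99.8% of these divisors were whole numbers within 0.01. The divisor was seldom the length of the gene itself. Of 7026 genes with a single transcript, 0.840% had a divisor within 1% of their own length, and for CHI1 the length was 863 bases and the divisor 73. For those 13950 genes the deposited values compare libraries within a gene but are not FPKM of the gene. For the rest the divisor differed between libraries by more than the tolerance, and how their values were made is not given in the sources used here.

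The plan made before the data were examined had assumed FPKM in that table. Gene values were instead summed from the transcript FPKM by gene name, a choice made before the groups were compared, and the deposited table became an alternative. The tables list 31688 genes and 59106 transcripts. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), by a two-sided moderated test with a mean-variance trend. Genes and transcripts entered with a mean FPKM of at least 1 over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. Members of lists are counted as higher or lower by the sign of the mean log2 difference, which for EXP2 and psbI is opposite to that of the mean FPKM. Differences are on the log2(FPKM + 1) scale, which understates the change of low genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

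The files and the reference gene table (assembly DVS_A1.0, used for names only) give symbols and synonyms but no product names, and 23518 of the 31688 gene identifiers matched a symbol of that table. The 30 gene lists fixed before the data were examined were patterns of product names. Of these, 2 matched any name, 1 each (a synonym chitinase and a synonym expansin), and 0 reached 5 members, so none could be tested. In their place 11 lists of gene symbols were written after the files were seen and before the groups were compared. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation, on ranks and with fry. Further groups built from synonyms, and the adjustment over the named nuclear genes alone, were chosen after the values were seen. The adjustment of genes over a list alone was not part of the plan, and it was not corrected for the number of lists.

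The rule for named genes was fixed in advance. It takes the 8 largest rises and the 8 largest falls among genes with product names past the threshold, members of the lists, and, where fewer than 5 genes pass in a direction, the 8 named genes with the smallest p in that direction as not having passed. With no product names, symbols were used, and counting synonyms as names was decided after the values were seen.

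The test was checked on simulated data, with the means and spreads of these libraries and 200 altered features. Features were drawn independently, and those altered were taken from features with a mean log2(FPKM + 1) above 3, so recovery among lower ones was not measured. Of 50 genes at each size among 17355, it recovered 8% at 1.5-fold, 52% at 2-fold, 90% at 4-fold and 100% at 8-fold, and called 5 unaltered genes. Among 26605 transcripts it recovered 2%, 18%, 76% and 88%, and called 6 unaltered ones. A simulated shift of 0.5 on the log2 scale in the abscisic acid list was recovered by camera with an adjusted p of 8.91e-08, a value that correlation between real genes would weaken.

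Alternatives covered the pseudocount, the filter, the scaling, the variance model, library weights, a block by replicate number, each library left out, voom on approximate read equivalents (assuming reads of 150 bases), a minimum size of the difference, and the set tests. Others were added after seeing the data: annotated transcripts only, the chloroplast share as a covariate, and the deposited gene table for the lists.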

Results

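The series asked how defence genes of orange fruit respond to the antagonist yeast when it is enhanced with salicylic acid. Expression was measured in 3 albedo libraries with the yeast and salicylic acid and in 3 with the yeast alone. Depth was 5.002, 5.24 and 4.78 gigabases in replicates 1 to 3 with salicylic acid, and 4.11, 4.87 and 4.60 gigabases in replicates 1 to 3 with the yeast alone. The group means were 5.01 ± 0.228 and 4.53 ± 0.384 gigabases (SD, n = 3 each). Between 17017 and 17586 genes had an FPKM of at least 1 in a library. Correlations across genes were 0.968 to 0.977 over the 6 pairs of libraries within groups and 0.964 to 0.981 over the 9 pairs between groups.

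Adding salicylic acid to the yeast was compared with the yeast alone. The pectinesterase gene PECS-2.1, whose product removes methyl groups from cell wall pectin, had the smallest p of any named gene. It stood at 835 ± 139 FPKM with salicylic acid and 395 ± 54.2 FPKM with the yeast alone (SD, n = 3 each), a ratio of 2.11, and was higher in all 3 libraries with salicylic acid than in any without. The log2 difference was 1.07 (SE 0.18, 95% interval 0.67 to 1.47), with an adjusted p of 0.531 in limma over all genes, so it did not pass. Adjusted over the 79 named nuclear genes alone, a choice made after the values were seen, its p was 0.0166. The files place it on NW_006257073.1 from 323645 to 326169 on the minus strand, with 2 exons. It belongs to a family of similar genes, and how reads shared within the family were assigned is not given in the sources used here.

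Of 17355 genes tested with limma, 1 passed the threshold, and it fell. This was MSTRG.22149, an unannotated single-exon locus with no strand on NW_006258927.1 from 1 to 829. It was listed at 0 in all 3 libraries with salicylic acid, and at 11.5, 14.4 and 11.8 FPKM in replicates 1 to 3 with the yeast alone (adjusted p = 0.000115). An unadjusted p under 0.05 was reached by 907 genes, or 5.23%, where 867.75 would be expected by chance. Of these, 529 were higher and 378 lower with salicylic acid, that is 58.3% higher, against 50.1% with median-of-ratios scaling and 50% with quantile normalization. The groups did not overlap in 1777 genes, 10.2% against the 10% that chance gives. For 90.8% of genes the 95% interval lay within 1 of 0 on the log2(FPKM + 1) scale, which for low genes does not exclude a 2-fold difference in FPKM. When transcripts of the reference annotation alone were summed, 0 genes passed in limma and 806 had an unadjusted p under 0.05. That sum leaves out MSTRG.22149 by construction, and the smallest adjusted p among the genes it holds was 0.0513.

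Cell wall genes had 5 tested members, of which 3 were higher and 2 lower by mean log2 difference, and 0 past the threshold over all genes. Adjusted over the list alone, 2 passed, PECS-2.1 and PECS-1.1. PECS-1.1, a second pectinesterase gene, stood at 50.9 ± 11.7 FPKM with salicylic acid and 33.2 ± 1.33 FPKM with the yeast alone (SD, n = 3 each), a log2 difference of 0.58. The other higher member, PME4, was at 1.20 against 0.998 FPKM, an order that turned without replicate 2 of the yeast alone (1.22 FPKM). The polygalacturonase gene PG was at 13.6 against 15.0 FPKM (13.4 without replicate 3 of the yeast alone) and the expansin gene EXP2 at 266 against 265 FPKM, with a log2 difference of -0.04. The order of the mean FPKM of EXP2 also turned with 1 library left out. The list did not pass as a set, with an adjusted p of 0.122 in camera and an adjusted p of 0.463 with an estimated correlation. Without replicate 3 of the libraries with salicylic acid its adjusted p was 0.0200, and 0.348 with an estimated correlation.

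Genes of abscisic acid synthesis, breakdown and glucosylation had 8 tested members, 5 higher and 3 lower, and 0 passed (adjusted p of the list 0.548 in camera). NCED, whose product makes the committed step of abscisic acid synthesis, stood at 27.3 ± 13.2 against 16.3 ± 5.23 FPKM (SD, n = 3 each). ABA2, which acts later in the same synthesis, was at 11.3 ± 2.83 against 8.52 ± 1.04 FPKM (SD, n = 3 each). CYP707A1, which breaks the hormone down, was at 35.3 ± 7.06 against 26.1 ± 5.09 FPKM (SD, n = 3 each). In these 3 genes the groups overlapped. The lower members were AOG, at 6.40 against 7.19 FPKM, and CYP707A4 and CYP707A3, of the same breakdown family as CYP707A1, at 4.12 against 5.44 and 1.26 against 1.69 FPKM. For AOG and CYP707A4 this direction rests on 1 library, since the means with the yeast alone were 6.38 FPKM without its replicate 2 and 3.46 FPKM without its replicate 1. Among the higher members, NSY was at 9.31 against 8.62 FPKM, and 9.47 FPKM without replicate 2 of the yeast alone. CYP707A3 was the 1 member whose libraries did not overlap between the groups, each lower with salicylic acid than each without.

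Stress and defence-linked genes, of the symbol lists the closest to the question of the series, had 9 tested members, 5 higher and 4 lower. Of these, 0 passed (adjusted p of the list 0.888 in camera). The planned lists of salicylic acid signalling, pathogenesis-related proteins, WRKY transcription factors and NLR disease resistance proteins matched 0 names. Defence genes of those kinds were therefore not tested as lists. CHI1 stood at 492 ± 47.4 FPKM with salicylic acid and 379 ± 136 FPKM with the yeast alone (SD, n = 3 each). The dehydrin gene DHN was at 496 ± 42.8 against 627 ± 78.2 FPKM (SD, n = 3 each), with each library with salicylic acid below each without. HSP90, a chaperone gene, was at 515 against 472 FPKM, and the glutathione transferase gene GSTU1 at 233 against 239 FPKM, an order that turned without replicate 3 of the yeast alone (212 FPKM) or replicate 2 with salicylic acid (248 FPKM). The order of the mean FPKM also turned with 1 library left out for LEA5, TIL, VPE and CHI of this list. CHI, at 1.26 against 1.03 FPKM, is counted as well in the flavonoid group that was built later from synonyms. With no product name, its place in either list rests on the symbol alone. Ethylene receptors and transcription factors had 5 tested members, 2 higher and 3 lower, and 0 passed (adjusted p of the list 0.392). For both higher members, EIL1 and ETR2, the order of the mean FPKM turned with 1 library left out. Among them the transcription factor gene EREBP was at 41.9 against 53.7 FPKM and the receptor gene ETR1 at 49.0 against 51.4 FPKM.

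**Figure D1:**
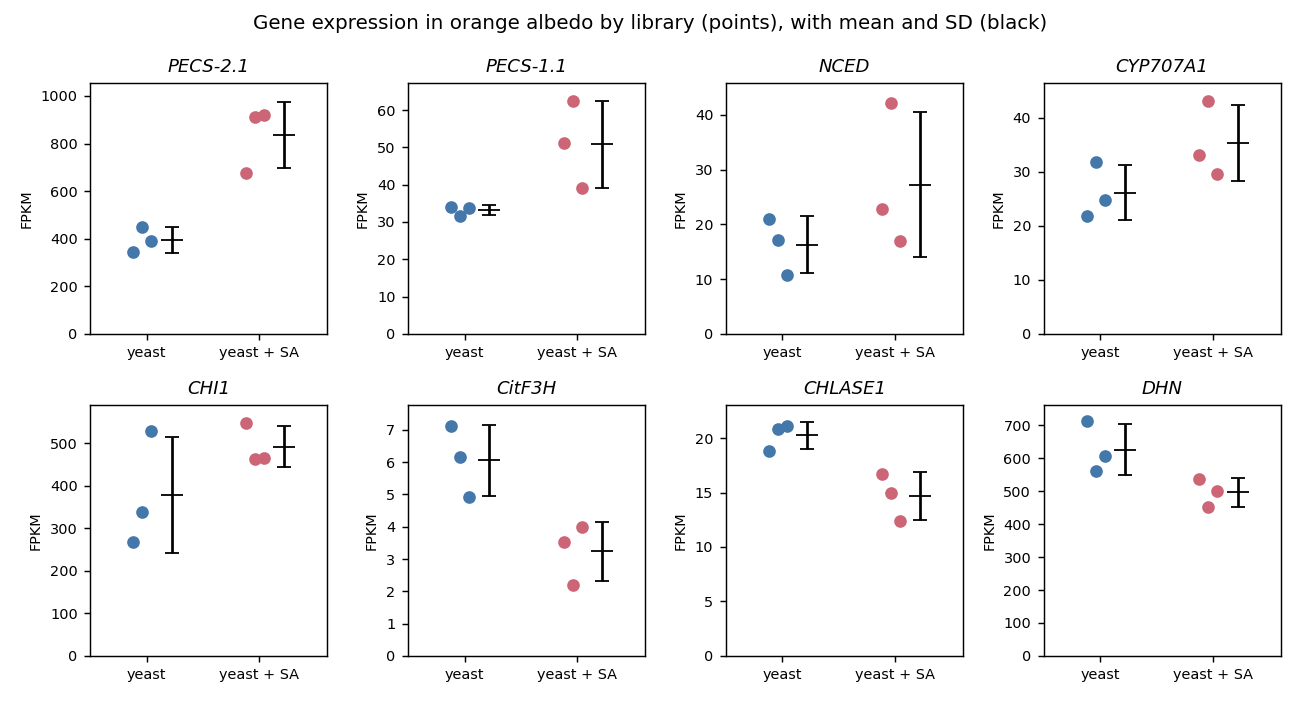
FPKM (vertical axis, linear from 0) of 8 named genes in the 6 albedo libraries, with the yeast alone on the left and the yeast with salicylic acid on the right of each panel; coloured points are libraries, and the black mark and bar are the mean and SD. PECS-2.1 lies between 343 and 451 FPKM with the yeast alone and between 675 and 918 FPKM with salicylic acid, while the groups overlap for NCED, CYP707A1 and CHI1.

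Of the 6 lists tested as sets, 0 were called by camera with either correlation, on ranks or by fry. Among lists too small for a set test, 0 genes passed over all genes. The jasmonate list had 1 tested gene, AOS, at 116 against 118 FPKM (110.0 without replicate 2 of the yeast alone). The phenylpropanoid list had 3, 2 higher and 1 lower. C4H1 was at 31.7 against 26.8 FPKM, CAD at 118 against 116 FPKM and C4H2 at 262 against 286 FPKM. For CAD the order of the mean FPKM turned with 1 library left out. The terpene and mevalonate list had 2, both lower, with TPS1 at 43.0 against 55.7 FPKM. The list of nuclear photosystem I subunits and chlorophyllase had 3, 1 higher and 2 lower. Of these, the chlorophyllase gene CHLASE1, at 14.7 ± 2.20 against 20.3 ± 1.24 FPKM (SD, n = 3 each) and a log2 difference of -0.45, passed when adjusted over the list alone. For the higher member, PSADB, and for PSAE the order of the mean FPKM turned with 1 library left out.

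Genes of the chloroplast genome were compared as well. Their share also depends on how much chloroplast RNA the library preparation kept, so it does not measure green tissue in the excised albedo. The planned list of green tissue markers matched 0 names. Its share of covered bases was 0.0992%, 0.0301% and 0.0376% in replicates 1 to 3 with salicylic acid, and 0.0689%, 0.0487% and 0.109% with the yeast alone. The list of its photosynthesis genes had 11 tested members, 6 higher and 5 lower (adjusted p 0.580 in camera). The ribosomal protein list had 11, 3 higher and 8 lower (adjusted p 0.392), and the list of RNA polymerase and other genes had 4, 2 higher and 2 lower. No member passed. Without replicate 1 of the libraries with salicylic acid, the photosynthesis and ribosomal lists were lower with salicylic acid, with adjusted p-values of 0.0352 and 0.0172, and an adjusted p of 0.432 for both with an estimated correlation.

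The other genes named by the rule did not pass either. The invertase gene Cs-bFruct1 (LOC102621775) stood at 28.2 against 23.1 FPKM, and the chloroplast gene rps15 at 2.97 against 2.15 FPKM. Lower with salicylic acid were UGT3, at 125 against 151 FPKM, and PMEI/InvI (LOC102624882), at 52.3 against 83.1 FPKM, and in both the groups overlapped. PMEI/InvI was at 119, 49.2 and 80.9 FPKM in replicates 1 to 3 of the yeast alone. Its log2 difference of -0.57 was -0.27 without replicate 1 and -0.90 without replicate 2 of the yeast alone. The chloroplast gene petG was at 3.45 against 5.08 FPKM. The flavonoid genes CitF3H (LOC102617426) and ANS (LOC102577958) were at 3.24 against 6.06 and at 0.637 against 1.48 FPKM. The first of the values for ANS was 0.301 FPKM without replicate 3 with salicylic acid. Log2 differences of CitF3H and ANS were -0.75 and -0.62.

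Single transcripts were compared as well as gene totals. Of 26605 transcripts tested with limma, 9 passed, 4 higher and 5 lower with salicylic acid, and 1379, or 5.18%, had an unadjusted p under 0.05. Of the 9, 1 is the only transcript of MSTRG.22149, the locus that passed as a gene. The other 8 belong to genes with further transcripts, whose totals did not pass and had the sign of the transcript in 7 genes and the opposite sign in 1. Each total holds the transcript itself, so a shared sign does not show that the other transcripts moved with it. Absolute log2 differences were 0.039 to 0.81 for these totals and 1.98 to 4.90 for the transcripts. The non-coding transcript XR_001507761.2 of LOC102630635 fell, from 35.8 ± 4.71 to 0.227 ± 0.0539 FPKM (SD, n = 3 each; adjusted p = 0.00126), while the total of its gene differed by -0.04 on the log2 scale. Transcript XM_025099338.1 of LOC102626016 was listed at 0 in all libraries with salicylic acid and at 15.8, 18.4 and 22.02 FPKM with the yeast alone (adjusted p = 0.00388), with a log2 difference of -0.78 in the gene total. In the other direction, MSTRG.17199.3 of LOC102626649 was at 10.5, 9.38 and 11.04 FPKM with salicylic acid and listed at 0 without it (adjusted p = 0.00505), with 0.47 in the gene total. MSTRG.16901.3 of LOC102625565 was at 7.33, 6.20 and 10.5 FPKM with salicylic acid and listed at 0 without it (adjusted p = 0.0360), while its gene total went the other way, with -0.14. The number that passed was 28 without replicate 1, 4 without replicate 2 and 1 without replicate 3 of the libraries with salicylic acid, and 5, 3 and 1 of these were among the 9. It was 5 with a pseudocount of 0.1 or with no filter, 4 with a mean FPKM of at least 5, and 2, XR_001507761.2 and XM_025099338.1, with the chloroplast share as a covariate, which was added after seeing the data. With a block by replicate number, 0 passed in limma.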

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

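The restriction to annotated transcripts, the chloroplast share as a covariate and the deposited gene table for the lists were chosen after the data were seen. The gene count was 1, and became 2 with a pseudocount of 0.1, robust variance, library weights, the replicate block or the deposited gene table. It was 0 with annotated transcripts only (limma, 806 at an unadjusted p under 0.05), a setting that leaves out MSTRG.22149 by construction. Leaving out 1 library gave 1 to 5 genes, with 5 without replicate 2 of the yeast alone and 2 without any 1 library with salicylic acid. MSTRG.22149 passed in all 18 alternatives that hold it. PECS-2.1 passed in 0 of 19, with log2 differences of 0.97 to 1.22. The lists called were 0, and 0 to 2 with 1 library left out, and these calls were lost with an estimated correlation (adjusted p 0.432, 0.432 and 0.348). The 16 genes named by the rule kept their direction and stayed short of the threshold in all 299 results under the alternatives. Of 70 results for 4 identifiers outside it, 66 kept direction and side, and 4, of LOC102611859 and LOC102624118, kept direction and newly passed. Transcripts past the threshold, 9 in all, were 5 with a pseudocount of 0.1 or with no filter, 4 with a mean FPKM of at least 5, 2 with the chloroplast share as a covariate, and 1 to 28 with 1 library left out. With the replicate block 0 passed in limma, with 1475 at an unadjusted p under 0.05 and all 9 in the same direction. The labels do not state that equal numbers pair the samples, so the plan had no block in the main test. Deviations of libraries with the same number correlated at 0.114, 0.188 and -0.009. Those with different numbers correlated at -0.248 to 0.140. With so few pairs these values neither show nor exclude pairing. The causes of these shifts were not tested. At this depth and number of libraries, 52% of simulated 2-fold differences in genes with a mean log2(FPKM + 1) above 3 were recovered.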

Other observations

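The groups built from synonyms, the splits of unannotated loci, and the tests of other transcripts, of read numbers and of the first component were chosen after the results were seen. Carotenoid synthesis genes had log2 differences from -0.04 to 0.12 over 7 tested genes and 0 past the threshold. VDE, which gave the 0.12, and NSY are also counted as higher members of the abscisic acid list, so these lists overlap. Flavonoid synthesis had 3 tested genes, 1 higher and 2 lower, 0 past the threshold over all genes and 1, CitF3H, adjusted over the list alone. The higher gene is the same CHI that is counted in the stress and defence-linked list. The group of invertases, an inhibitor and glgC had 5, 3 higher and 2 lower, and ethylene genes with synonyms had 8, 4 higher and 4 lower, none past the threshold. Of 2 genes whose synonyms name chitinase and beta-glucanase, the first (LOC102627878) was at 1.76, 1.20 and 1.99 FPKM with salicylic acid and 0.810, 2.48 and 0.813 FPKM with the yeast alone. The second, gns1 (LOC102614791), was at 6.10, 6.02 and 1.64 FPKM with and 1.66, 11.9 and 2.99 FPKM without salicylic acid, and the order of its means turned without replicate 2 of the yeast alone or replicate 3 with salicylic acid. The named gene of highest expression was aco-1 (LOC102577997), at 3884 to 5949 FPKM over the 6 libraries. LEA5 ranged from 3247 to 6521 FPKM, highest in replicate 1 of the yeast alone.

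LOC102611859, LOC102624118 and LOC102625710 fall outside the naming rule and were chosen after their values were seen. Their log2 differences were -1.99, 3.10 and 1.15, with adjusted p-values of 0.0629, 0.306 and 0.531 in limma. In LOC102611859 and LOC102624118 the difference came from an unannotated transcript, MSTRG.21238.1 and MSTRG.9187.1, rather than from the annotated model. The 2 transcripts summed for LOC102624118 lie on opposite strands. For LOC102611859 a transcript on the minus strand was summed with another that has no strand. These totals may thus not be expression of the annotated genes. The total of LOC102624118 was at 19.2, 4.06 and 7.38 FPKM in replicates 1 to 3 with salicylic acid, a mean of 10.2 FPKM that was 5.72 FPKM without replicate 1.

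The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 1 gene past the threshold. Counting itself, 9 of the 10 splits gave at least as many, and the highest other split gave 4. At an unadjusted p under 0.05 the real split gave 907 genes, and 4 splits, counting itself, gave at least as many, the highest other 2302. For transcripts past the threshold it gave 9, and 5 splits, counting itself, gave at least as many, the highest other 58. Unannotated loci at an unadjusted p under 0.05 numbered 120 of 1088, or 11.03%, against 4.73% of protein-coding genes. Counting the real split, 2 splits gave at least as many, the highest other 164. In each of the 10 splits the share of unannotated loci was above that of all other genes. It was 11.03% against 4.84% in the real split. With replicates 1 and 3 with salicylic acid and replicate 1 of the yeast alone against the rest, it was 7.63% against 2.96%. The contrast is thus not particular to the salicylic acid comparison. The split of replicate 1 with salicylic acid and replicates 1 and 3 of the yeast alone against the rest gave the 2302 genes and 58 transcripts, which may reflect a structure of the samples that the labels do not give. It was picked as the highest of 10 after the counts were seen, whether it exceeds chance was not tested, and that these 3 libraries had the highest chloroplast shares was noticed afterwards.

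Transcripts listed at 0 in all libraries of one group and at 2 FPKM or more in all of the other numbered 18. Of these, 12 were present with salicylic acid and listed at 0 without it, and 6 were the other way round. Counting the real split, 2 of the 10 splits gave at least as many, the highest other 31. Too few reads is argued against as the account of all 18. Averaged over the 3 libraries where each is present, they had 58.4 to 1581 read equivalents, and single libraries can lie lower. Over 59106 transcripts at equal levels, Poisson sampling of 150-base reads gives 0.00554 such transcripts with each read independent and 0.0755 with 2 reads as 1. With 10 reads as 1 it gives 3.11, above the bound of 1 set for this test, so a few of the 18 stay open if reads were that heavily duplicated. Reads assigned to other transcripts of the same gene may account for part of the pattern: in the 17 whose gene has others, the median absolute log2 difference of the gene total was 0.321 (95% interval 0.137 to 0.779), against 2.84 for the transcripts. That interval holds the bound of 0.5 set for this test, and 11 of the 17 lay under it and 6 at or above, so it stays open, as does an effect of salicylic acid on transcript choice, which was not tested.

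The first principal component, 29.6% of the variance, was at -9.40, 28.6 and 14.0 in replicates 1 to 3 with salicylic acid and -34.7, 12.6 and -11.2 with the yeast alone, and its relation to the groups was not tested. It correlated with depth (r = 0.850, exact permutation p = 0.0306, adjusted 0.0667 over 3 relations; rho = 0.771, exact permutation p = 0.103, adjusted 0.154), but r was 0.13 without replicate 1 of the yeast alone and replicate 2 with salicylic acid, so the relation rests on those libraries. Over genes with a mean FPKM of at least 20, r was 0.837 (exact permutation p = 0.0444, adjusted 0.0667), and -0.05 without the same libraries, so depth acting through genes of low expression is neither excluded nor shown. With the chloroplast share r was -0.683 (exact permutation p = 0.142, adjusted 0.142) and rho -0.829 (exact permutation p = 0.0583, adjusted 0.154), and r was -0.961 without replicate 3 of the yeast alone and replicate 1 with salicylic acid.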
